A study of Mus musculus with 2 samples.

How the data were processed

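The series holds 2 mouse 10x Genomics single-cell RNA libraries from bone marrow, each made from a pool of 3 naive mice on the C57BL/6 background. One library, called the marrow library here, was made from CD45+ CD3- Ly6G- cells. The other, called the Car1-GFP library, was made from CD45+ cells of reporter mice that expressed GFP under Car1. The design text states 10000 sorted cells loaded. According to the submitters' processing notes, reads were processed with Cell Ranger 2.1 and Seurat 2 on mm10. The deposited values are UMI counts per gene and barcode for 27998 genes; every value in both matrices was checked to be a whole number, and no deposited annotation of cells was used here. Groups were taken from the sample labels alone. Positions of Car1 and Car2 come from the GENCODE M21 annotation of mm10, 1-based, in which 27645 of the 27998 gene identifiers were found.

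The marrow library held 6458 barcodes with at least 593 UMIs each, and the Car1-GFP library held 2522 with at least 4697. Barcodes with under 500 UMIs, of which there were 0, or with 10% or more mitochondrial UMIs were left out: 19 (0.294%) of the marrow library and 122 (4.84%) of the Car1-GFP library. Doublets were called per library with Scrublet as run by scanpy, and removed where the caller marked at least 0.5% of the cells. It marked 171 (2.66%) in the marrow library, which were removed, and 9 (0.375%) in the Car1-GFP library, where none were removed. This left 6268 marrow cells with 8303633 UMIs (median 1031 per cell, 543.5 genes) and 2400 Car1-GFP cells with 42795219 UMIs (median 15512.5, 3346.5 genes). The Car1-GFP cells were therefore 15.0 times deeper. A count of 0 was set against a floor of 3 counts, which is 0.361 CPM in the marrow library and 0.0701 CPM in the Car1-GFP library. Where that floor lay above the value of the other side, no ratio was formed.

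With 1 library per group there is no spread between replicates, so no test between groups was made. Counts of the kept cells were summed per library and divided by the library total (CPM). Each ratio of Car1-GFP over marrow carries a 95% exact binomial interval for a pair of counts, each CPM an exact Poisson interval and each share of cells an exact binomial interval; all of them cover counting error only, not differences between mice, sorts or preparations. Genes with at least 20 UMIs over both sides were called measured, and a size of 2-fold was used to count higher and lower genes. For 20 gene lists fixed before the data were examined, the median log2 ratio of the measured members was set beside 10000 random lists of the same size, matched over 20 bins of mean expression. A bootstrap interval of each median was taken from 2000 draws of the members. The resulting percentile describes these libraries and is not a test. The lists were carbonic anhydrases, heme synthesis, iron handling, globins, glycolysis, tricarboxylic acid cycle, oxidative phosphorylation, nucleotide and one-carbon synthesis, pentose phosphate pathway, antioxidant enzymes, cholesterol synthesis, eicosanoid and histamine synthesis, mast cell, basophil, erythroid transcription factors, cytokine receptors, cell cycle, MHC class II, dissociation stress and sex-linked genes. Of their members 1, the hemoglobin chaperone Ahsp, had no row in the gene table, as did 4 of the cell class markers.

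Named genes followed a rule fixed at the same time. It took genes with a mean of at least 50 CPM, apart from mitochondrial, ribosomal protein, globin and immunoglobulin genes, and from these the 15 highest and 15 lowest ratios. Car1 and Car2 were always named, and up to 4 measured members of each list with the largest absolute ratios. Within a cell class it took the 10 highest and 10 lowest genes with at least 50 UMIs, with Car1, Car2, Kit, Gata1, Gata2 and the genes of the basophil/mast cell and erythroid sets. Over classes it took up to 4 members of each metabolic list. Values of 3 list members that the rule names are not reported here. Genes outside this rule are marked as chosen after their values were seen.

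Each library was clustered alone in scanpy 1.11.5 (Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2). Genes in at least 3 cells were normalised to 10000 per cell and logged, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 with seed 1 were used. The carbonic anhydrases and the members of the metabolic lists, 150 genes in all, were left out of the clustering. Markers of 17 cell classes were fixed before the data were examined; the rule that turned them into names was set after the data were seen. A cluster took the class with the highest mean log2 ratio of its markers, with 10 CPM added, over the marrow cells outside the cluster. It needed at least 3 markers at 2-fold with at least 3 UMIs each. No other class could have more markers among its top 10 genes by fold, taken from genes with at least 20 UMIs. Within its own library, no other class could have 3 or more and more markers than the chosen class among the top 10. Clusters that failed stayed unnamed: 16 of 2400 Car1-GFP cells (0.667%) and 0 of 6268 marrow cells. Names are rebuilt from these markers and mean "-like" throughout.

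To compare shares of cells with a UMI, each cell was thinned to 1000 UMIs. This used 3271 marrow cells and left out 2997, and used all 2400 Car1-GFP cells. For co-detection, a cell counted as positive with 1 UMI of a set: 9 basophil/mast cell genes (Cpa3, Ms4a2, Fcer1a, Hdc, Tpsb2, Tpsab1, Cma1, Mcpt8, Prss34) and 7 erythroid genes (Klf1, Gata1, Epor, Ermap, Cnrip1, Aqp1, Mfsd2b). Within-class ratios were formed only for a class with at least 50 cells in each library.

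The methods were tested on simulated data of the same depths. Of genes set 4-fold and 3-fold apart, 100% and 99% were recovered at 2-fold; 1.90% of 12593 unchanged genes passed 2-fold, and 95.7% of the intervals on 12582 genes held the true ratio. At the depths of the late erythroid classes these values were 100%, 91%, 6.85% of 10398 genes and 96.8% of intervals on 10373 genes. Both runs drew independent Poisson counts of summed profiles from the mean profile of the 2 libraries. This is the model behind the intervals, so coverage near 95% follows from the design. Spread between cells was not simulated, so the runs do not show how the intervals behave with it. Of random lists with no change, 13% fell outside the 5th to 95th percentile where 10% should, and simulated independent sets gave co-detection ratios of 0.998 and 1.01.

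Alternatives fixed before the data were examined were all deposited barcodes, at least 1000 UMIs per cell, doublets kept, edgeR 4.0.16 TMM factors, DESeq2 1.42.0 size factors, totals without globin, mitochondrial and immunoglobulin genes, equal weight per cell, gene minimums of 1 and 100 UMIs, unmatched random lists, Leiden resolutions 0.5 and 2, joint clustering after thinning, clustering with the metabolic genes kept, another seed, thinning to 500 or 2000 UMIs or not at all, 2 UMIs of a set, Cpa3 and Ms4a2 alone, and TMM factors within a class. Chosen after seeing the data were a merge of both erythroid classes, a comparison of erythroid progenitors with at least 1000 UMIs between libraries, a clustering of the Car1-GFP library without the co-detection sets, and metabolic lists without members that are also markers of the class. The clustering without the co-detection sets also left out the mast cell and basophil lists and the metabolic genes. Figures were drawn with matplotlib 3.10.9.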

Results

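The data are 2 single-cell libraries of mouse bone marrow, 1 per group, each from a pool of 3 mice: CD45+ CD3- Ly6G- cells (6268 kept of 6458 barcodes, median 1031 UMIs) and CD45+ Car1-GFP cells (2400 kept of 2522 barcodes, median 15512.5 UMIs). The design states 10000 cells loaded. S100a8 and S100a9, the calprotectin subunits of neutrophils and monocytes, made up 11.1% of marrow UMIs and 0.0118% of Car1-GFP UMIs. Globin transcripts made up 0.213% and 1.19%, ribosomal protein transcripts 20.3% and 34.6%, and mitochondrial transcripts 2.19% and 3.45%.

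The first question was which transcripts set the Car1-GFP cells apart from the broader marrow gate. Heme synthesis and globin genes stood at higher values, and basophil, cytokine receptor and MHC class II genes at lower values. Car1 (ENSMUSG00000027556, mm10 chromosome 3, 14766216 to 14808368, minus strand), a cytosolic carbonic anhydrase and the gene behind the reporter, was 594 CPM in the Car1-GFP library and 102 CPM in the marrow library, a log2 ratio of 2.53 (2.44 to 2.63) or 5.79-fold, and 3.64 with every cell weighted equally. Its neighbour Car2 (ENSMUSG00000027562, chromosome 3, 14886273 to 14900770, plus strand), which encodes another cytosolic carbonic anhydrase of red cells, differed more: 3246 against 191 CPM, log2 4.08 (4.01 to 4.16), 17.0-fold.

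The 15 named genes with the highest ratios included the blood group protein gene Rhd (4.55), the cholesterol-binding Tspo2 (4.17), the repressor Gfi1b (3.94), Cldn13 (3.97), Hebp1, a heme-binding protein (3.74), and Blvrb, a biliverdin reductase (3.73; 1134 against 85.5 CPM). The others were Gm15915 (4.74), Sdsl (4.57), the AP-1 subunit Jun (4.32), Car2, the glutathione transferase Gstm5 (4.02), the lamin gene Lmna (3.89), the amino acid transporter Slc38a5 (3.73), Cited4 (3.66) and the asparagine synthetase Asns (3.62). At the low end stood Cd74, the invariant chain (-11.48), and the granulocyte genes Wfdc21 (-10.96), Cd177 (-10.10), S100a8 (-9.93; 69.4 against 67648 CPM), Pglyrp1 (-9.81), S100a9 (-9.81) and Ltf (-9.79). Ly6d (-10.49), the NADPH oxidase subunit Cybb (-10.17), the basophil protease Mcpt8 (-9.91) and the myeloid factor Cebpb (-9.80) were also among them. The remaining 4 rested on 1 to 3 UMIs in the Car1-GFP library: the immunoglobulin joining chain Jchain (-12.84, interval -18.15 to -10.36, 1 UMI), the integrin Itgam (ENSMUSG00000030786; -12.39, -17.69 to -9.91, 1 UMI), Sorl1 (-12.10, -17.40 to -9.62, 1 UMI) and Cox6a2 (-10.56, -12.84 to -9.01, 3 UMIs).

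Over 12076 measured genes, 2682 were at least 2-fold higher in the Car1-GFP library, 3946 at least 2-fold lower and 5448 within 2-fold; 43 were at least 16-fold higher and 1069 at least 16-fold lower, and 256 had 0 counts in 1 library. The median log2 ratio was -0.23. Another scaling moves this split: TMM factors add 0.389 to every log2 ratio and give 3720 higher and 3190 lower, and DESeq2 size factors add 0.385 and give 3708 and 3197. All ratios here divide by the library total and are to be read relative to that shift.

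The metabolic lists separated by pathway. Heme synthesis, the route that makes the prosthetic group of hemoglobin, had 8 of 9 members at least 2-fold higher and 1 lower (median 3.09, percentile 100), with Alad (3.60), Urod (3.23) and the erythroid isoform Alas2 (3.12) higher and the housekeeping isoform Alas1 (chosen after its values were seen) lower (-2.88). Carbonic anhydrases had 6 of 8 measured members higher and 2 lower (median 1.94, percentile 99.97); after Car1 and Car2 came Car13 (2.44), Car7 (1.96, -0.69 to 7.33, 1 marrow UMI), Car3 (1.93) and Car9 (1.12), with Car5a (-2.55) and Car5b (-3.49), which encode mitochondrial enzymes, lower. Car3, Car7, Car9 and Car13 stood under 6 CPM in the Car1-GFP library. Iron handling had 5 of 9 higher and 0 lower (1.25, 97.47), among them Slc25a38 (2.42), Slc11a2, the iron transporter DMT1 (2.31), Fth1 (1.88) and Steap3 (1.84). All 4 measured globin genes were higher (2.45, 99.99): Hbb-bs 3.10, Hbb-bt 2.90, and Hba-a1 2.0 and Hba-a2 1.59, whose near-identical sequences leave their single values uncertain.

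The tricarboxylic acid cycle had 11 of 17 members higher and 0 lower (median 1.44, percentile 99.85; Idh3a 2.34, Mdh2 2.30, Sdhc 1.85, Suclg1 1.81). Nucleotide and one-carbon synthesis had 16 of 22 higher and 0 lower (1.24, 99.87; Impdh2 2.45, Tyms 2.39, Dhodh 2.22, Mthfd1 2.03). Oxidative phosphorylation had 9 of 18 higher and 1 lower (1.03, 92.96; Uqcrc2 2.33, Atp5b 2.18, Uqcrc1 1.89, Uqcrfs1 1.61). In glycolysis 5 of 15 were higher and 7 lower (-0.94, 2.08): Hk2 (-5.20), Pkm (-4.07) and the glucose transporter Slc2a1 (-2.57) were lower, the phosphofructokinase Pfkm (2.95) higher. Eicosanoid and histamine synthesis, used by basophils, mast cells and myeloid cells, had 1 of 8 higher and 6 lower (-3.31, 0.29), with Hdc, the histamine-forming enzyme (-7.04), Ptgs1 (-5.78), Alox5ap (-4.77) and Alox5 (-4.63) lower.

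Smaller differences were found in 3 lists. The pentose phosphate pathway had 2 of 7 higher and 2 lower (median -0.48, percentile 11.98; Pgd -1.83, G6pdx -1.72, Pgls 1.07, Rpia 1.04). Antioxidant enzymes had 4 of 11 higher and 0 lower (0.38, 51.3), led by Prdx2, the peroxiredoxin of red cells (3.20), Gclm (2.05), Sod2 (1.8) and Gpx4 (1.40). Cholesterol synthesis had 2 of 17 higher and 4 lower (Hmgcs1 -2.14, Pmvk 1.40), and its median of -0.13 has the opposite sign under TMM (0.26) and DESeq2 (0.25) scaling (percentile 66.4).

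Lineage lists bore on the progenitor named in the series title. Erythroid transcription factors had 5 of 10 higher and 0 lower (median 1.06, percentile 93.08; Gfi1b 3.94, Klf1 3.45, Gata1 3.14, Tal1 2.1). The basophil list had 0 of 10 higher and 9 lower (-4.10, 0.03): Mcpt8 -9.91, the protease Prss34 -9.29, Cebpa -6.37, and Cd200r3 with 0 UMIs, at least 107-fold lower. The mast cell list was mixed, with 2 of 10 higher and 5 lower (-1.29, 9.07): the IgE receptor chains Fcer1a (-4.03) and Ms4a2 (-3.80), the integrin Itgb7 (-2.68) and Mitf (-2.64) were lower. Chosen after their values were seen, Gzmb (2.08) and the transcription factor Gata2 (1.20) were the 2 higher ones, and the carboxypeptidase Cpa3 stood at 7.94 against 39.0 CPM (-2.30). The 262 Gzmb UMIs of the Car1-GFP library lay in 100 cells, with up to 41 in 1 cell. Cytokine receptors had 1 of 15 higher and 11 lower (-6.17, 0): Csf1r -8.00, Csf3r -7.90, Il7r -9.56 (1 UMI, -14.87 to -7.05) and Flt3 -7.59 (3 UMIs, -9.89 to -6.00), while the erythropoietin receptor Epor (chosen after its values were seen) was the higher one at 3.13.

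Of the remaining lists, cell cycle genes had 5 of 16 higher and 0 lower (median 0.85, percentile 86.3; Cdc20 1.63, Ccnb1 1.49, Mcm2 1.39, Mcm7 1.23). MHC class II, the antigen-presenting molecules, had 0 of 7 higher and 6 lower (-2.59, 0.35; Cd74 -11.48, H2-Aa -8.73, H2-Eb1 -7.83, Ciita -2.59). Dissociation stress, a set of immediate early and heat shock genes, had 6 of 10 higher and 2 lower (1.73, 99.98): Egr1 4.51, Jun 4.32 and Hspa1a 4.25 (uncertain apart from its near-copy Hspa1b) were higher and Zfp36 (-3.92) lower. In the sex-linked list (4.15, 100), the Y-linked genes Eif2s3y (at least 118-fold), Ddx3y (at least 73.9-fold), Uty (at least 17.7-fold) and Kdm5d (at least 11.1-fold) had 0 UMIs in the marrow library and higher values in the Car1-GFP library, and Xist was lower (-1.54). The labels give no sex, so sex and sort differ together between the libraries. Resampling the members of each list gave intervals of the median that included 0 for carbonic anhydrases (-0.77 to 2.53), iron handling (-0.06 to 2.31), glycolysis (-2.12 to 1.56), the pentose phosphate pathway (-1.72 to 1.04), antioxidant enzymes (-0.10 to 1.8), cholesterol synthesis (-0.68 to 0.67), mast cell (-3.22 to 0.46), dissociation stress (-1.11 to 4.25) and sex-linked genes (-1.54 to 6.88).

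**Figure D1:**
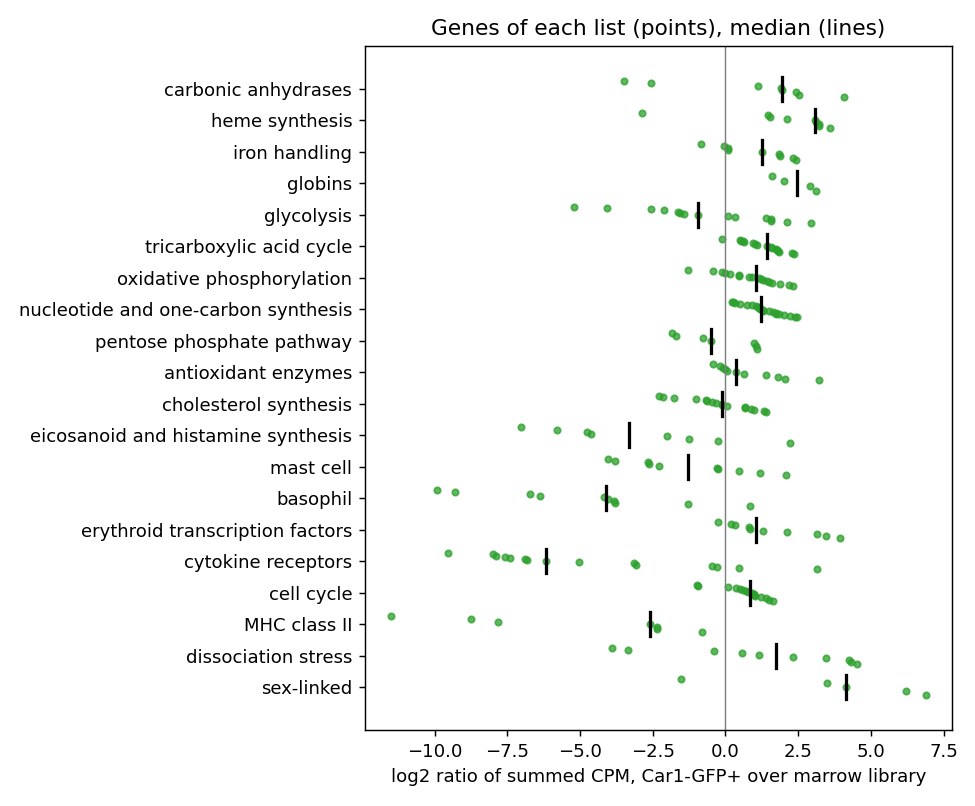
Log2 ratio of summed CPM, Car1-GFP over marrow library, for each measured member (points) and the median of each fixed gene list. Heme synthesis, with a median of 3.09, lies to the right, and cytokine receptors, with -6.17, to the left.

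The next question was which cell types each gate held. In the marrow library, neutrophil (2098 cells, 33.5%, 32.3 to 34.7) and monocyte cells (1678, 26.8%, 25.7 to 27.9) were the largest classes, followed by granulocyte-monocyte progenitor (735, 11.7%), plasmacytoid dendritic (528, 8.42%), and stem and multipotent progenitor cells (433, 6.91%). Late erythroid cells made up 270 (4.31%, 3.82 to 4.84), and the erythroid share was 7.36% with at least 1000 UMIs per cell and 6.94% when both libraries were clustered together. NK and innate lymphoid cells numbered 169 (2.70%), conventional dendritic cells 122 (1.95%), basophil/mast cells 109 (1.74%, 1.43 to 2.09), B lineage cells 100 (1.60%) and macrophages 26 (0.415%). At this setting the Car1-GFP library was almost wholly erythroid: 1925 erythroid progenitor (80.2%, 78.6 to 81.8) and 443 late erythroid cells (18.5%, 16.9 to 20.1), together 98.7% (98.1 to 99.1). There were also 16 megakaryocyte cells (0.667%) and 16 unnamed cells (0.667%), whose top genes within the library included the granulocyte genes S100a8 and Elane. The erythroid share depended on the clustering: 66.8% at Leiden resolution 0.5, 85.9% with metabolic genes kept, 89.5% at resolution 2, 90.8% with another seed and 99.8% with joint clustering. No Car1-GFP cluster was called basophil/mast cell. No marrow cluster was called erythroid progenitor at this setting, although its late erythroid cluster also held such cells.

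These shares are to be read with the gates and the 15-fold gap in depth, and a class found mostly in 1 library may reflect that library. The lowest Car1-GFP barcode had 4697 UMIs and the lowest marrow barcode 593, so small cells missing from the Car1-GFP matrix would change its shares. The marrow gate was set against Ly6G, yet an Ly6g UMI was found in 8.98% of its cells; Cd3e was found in 0.207%. Ptprc, which encodes CD45, was detected in 31.1% of marrow and 19.7% of the far deeper Car1-GFP cells (303 and 13 CPM).

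**Figure D2:**
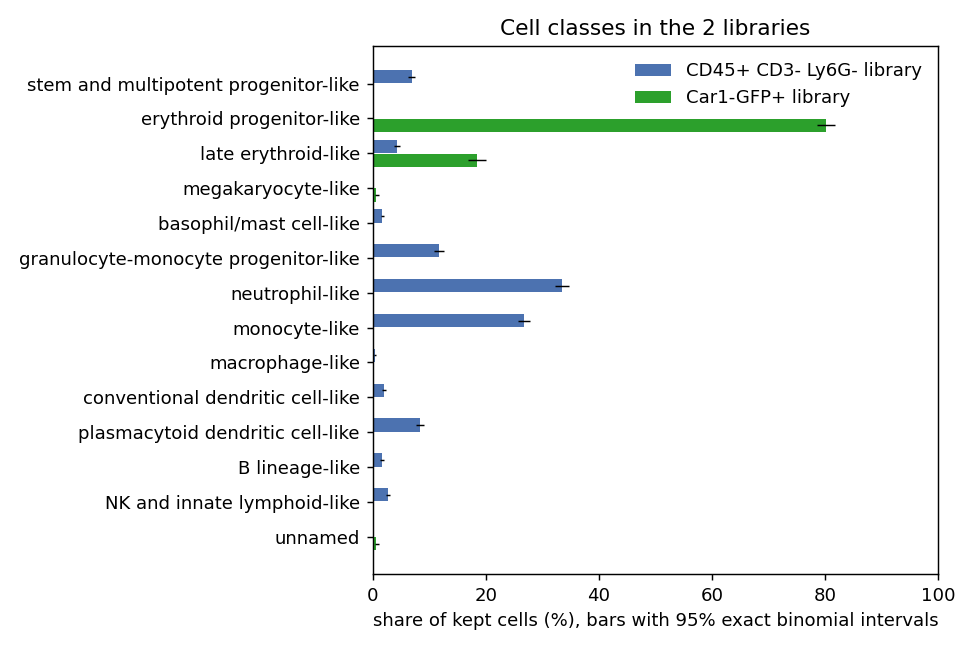
Share of kept cells in each named class, in percent, for the marrow and Car1-GFP libraries, with 95% binomial intervals. Neutrophil and monocyte cells lead the marrow library. At the main setting 98.7% of Car1-GFP cells fall in the erythroid classes, and 66.8% to 99.8% under other clusterings.

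Within the marrow library, Car1 transcripts were concentrated in erythroid cells. The cluster called late erythroid (cluster 7) held 702 of 851 Car1 UMIs (82.5%) with 9.86% of all UMIs, at 857 CPM (795 to 923), and 81.5% of Car2 UMIs at 1583 CPM (1498 to 1672). This cluster mixed stages: with at least 1000 UMIs per cell it split into 181 erythroid progenitor cells with 951 CPM of Car1 (879 to 1027; 653 UMIs) and 71 late erythroid cells with 445 CPM (346 to 565; 68 UMIs), and Car2 was 1452 and 1958 CPM. Stem and multipotent progenitor cells came next with 94.7 CPM of Car1 (71.5 to 123) and 213 CPM of Car2. Car1 was 16.5 CPM in granulocyte-monocyte progenitors, 12.8 (8.76 to 18.1) in neutrophils and 10.4 in monocytes. In basophil/mast cells 1 Car1 UMI (7.62 CPM, 0.193 to 42.5) and 2 Car2 UMIs (15.2 CPM) were counted, while NK and innate lymphoid cells had 204 CPM of Car2 (143 to 282) beside 11.3 CPM of Car1. In the Car1-GFP library, Car1 was 647 CPM (638 to 655) in erythroid progenitor and 394 (381 to 408) in late erythroid cells, whereas Car2 was 2875 and 4807 CPM.

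At an equal depth of 1000 UMIs, a Car1 UMI was found in 4.19% of marrow cells (3.53 to 4.93; 4.85% unthinned) and in 44.0% of Car1-GFP cells (42.0 to 46.0; 98.7% unthinned). Among marrow classes the share was 38.3% in late erythroid cells (67.8% unthinned, median depth 2569.5), 1.08% in neutrophils (median depth 1038.5) and 0 of 58 basophil/mast cells. Free RNA may limit the low values. S100a8, which erythroid and lymphoid cells should lack, had a UMI in 99.9% of marrow cells and 40.6% of Car1-GFP cells (median depths 1031 and 15512.5). Free RNA was not shown to be the source. In the Car1-GFP library a cluster of 181 cells, found without the co-detection sets, had 647 CPM of S100a8 against 31.0 CPM in the other cells. The erythroid classes were alike, with 32.1 CPM in erythroid progenitor and 28.0 CPM in late erythroid cells. They held 1090 and 238 of the 2968 S100a8 UMIs. The rest lay in the megakaryocyte and unnamed cells, and the unnamed cells had granulocyte genes among their top genes. The cluster of 181 cells therefore does not count against free RNA in erythroid cells. With the source not shown, the low Car1 values of neutrophils and monocytes were not read as expression in those cells, nor as free RNA.

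**Figure D3:**
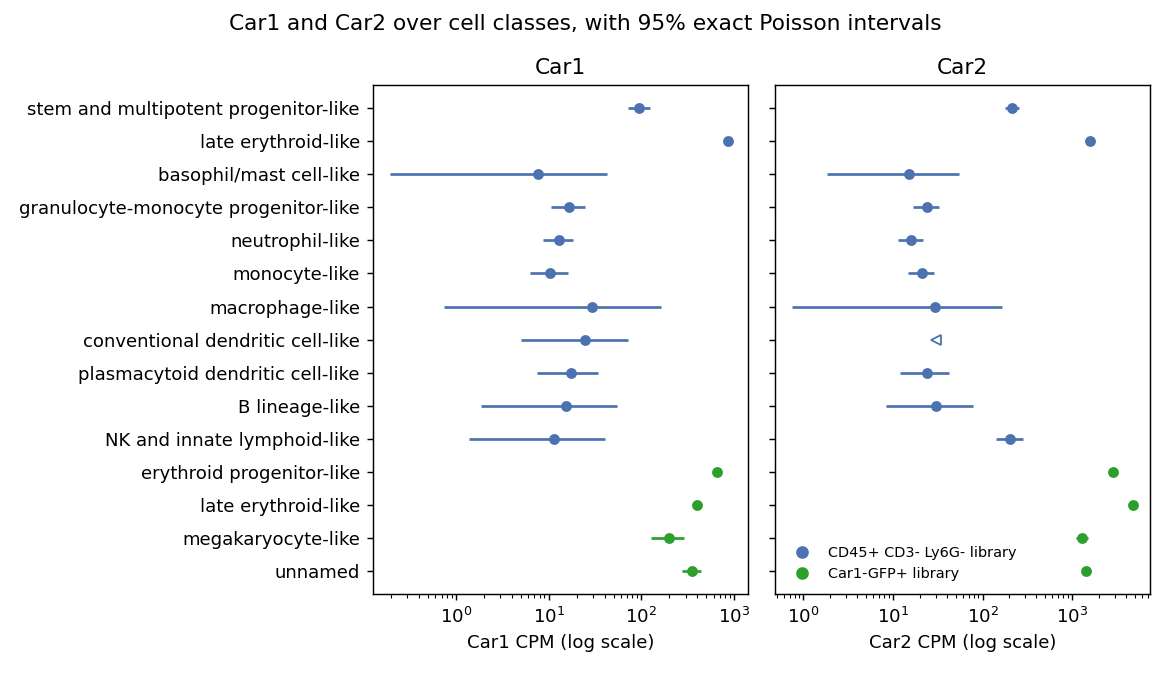
Car1 and Car2 in CPM (log scale) by cell class and library, with 95% Poisson intervals. In the marrow library the cluster called late erythroid, which also held erythroid progenitors, stands highest, at 857 CPM of Car1.

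Whether cells of 1 type differed between the gates was asked first of late erythroid cells, the class with at least 50 cells in both libraries at the main setting. Between Car1-GFP (443 cells; clusters 5, 6 and 9) and marrow (270 cells; cluster 7), Car2 was higher (1.60, 1.52 to 1.68) and Car1 itself lower (-1.12, -1.24 to -1.0; -0.61 with TMM factors). Kit, the stem cell factor receptor, was lower (-3.26, -3.70 to -2.82); Klf1 (0.74), Gata1 (0.56), Aqp1 (0.47), Epor (0.19), Mfsd2b (-0.43), Ermap (-0.75) and Gata2 (-0.85) were within 2-fold, and Gata2 had the opposite sign with both erythroid classes merged (0.84, 0.28 to 1.47). With the marrow cluster split by stage, at 1000 or more UMIs per cell, Car1 was -0.18 and Kit 0.76 (-1.76 to 6.08, 1 marrow UMI) between late cells, and Hbb-bs turned from 1.46 (1.42 to 1.51) to -0.54 (-0.59 to -0.49). Erythroid progenitors were also compared, a step chosen after seeing the data. Between them Car1 was -0.56 (-0.67 to -0.44), Car2 0.99, Kit -1.45, Gata2 0.94 (0.35 to 1.60) and Hbb-bs 3.41 (3.20 to 3.63). Kit and Hbb-bs would place the Car1-GFP progenitors later and Gata2 earlier, so these classes were not shown to be matched in stage. An Hbb-bs UMI was found in 2400 of 2400 Car1-GFP cells and in 620 of 6268 marrow cells, at their unequal depths. How much of the progenitor value was free globin RNA was not measured, so Hbb-bs is a weak guide to stage here.

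The 10 lowest genes within the unsplit class were Ly6d (-9.37, -14.70 to -6.84, 1 UMI), Pglyrp1 (-8.75, -11.82 to -6.85, 2 UMIs), Ltf (-8.74), Wfdc21 (-8.45), S100a6 (-8.32), S100a8 (-8.28), Lcn2 (-8.00), Ccl5 (-7.96, -11.05 to -6.03, 2 UMIs), F630028O10Rik (-7.93) and S100a9 (-7.89). The highest were the folate enzyme Aldh1l1 (at least 17.9-fold, 0 UMIs in marrow), Eif2s3y (at least 12.6-fold), and 8 that rest on 1 to 4 marrow UMIs: Hspa1a (3.99, 1.49 to 9.30), Dnase1l1 (3.79, 1.28 to 9.10), Apol8 (3.55, 1.04 to 8.86), Mnd1 (3.51, 1.0 to 8.82), Gm14198 (3.48, 0.98 to 8.80), Gstt2 (3.24, 1.37 to 6.30), Cdk5rap1 (3.22, 1.35 to 6.27) and Apool (3.21, 1.84 to 5.09).

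Of 9037 genes measured within the class, 1114 were at least 2-fold higher and 2483 lower (median -0.28), and under TMM factors 2341 and 1395. Heme synthesis had 6 of 9 higher and 1 lower (median 1.52) and cell cycle genes 5 of 16 higher (0.72), but between late cells with at least 1000 UMIs these medians were 0.07 and 0.00, and between erythroid progenitors 0.90 and 0.09. The tricarboxylic acid cycle had 7 of 17 higher (0.97; 1.26 between those late cells), oxidative phosphorylation 8 of 18 higher and 1 lower (0.91; 0.85) and dissociation stress genes 7 of 8 higher (2.0; 1.53, 2 of 4 measured higher). Some list medians had the opposite sign to that of the summed libraries. Glycolysis was 0.92 (5 of 11 higher, 1 lower) between those late cells and 0.40 between erythroid progenitors, against -0.94 summed. Iron handling was -0.96 and -0.57, against 1.25 summed. The bootstrap intervals of these glycolysis and iron handling medians included 0. Globins were -1.09 between those late cells but 1.58 between progenitors, against 2.45 summed. The mast cell gene Cpa3 had 30 UMIs in Car1-GFP and 4 in marrow late erythroid cells (-0.47, -1.97 to 1.5) of the unsplit class. With stages split at 1000 or more UMIs per cell, late cells had 30 and 0 UMIs. Erythroid progenitors had 307 and 4 (0.63, -0.74 to 2.52), so the direction was not settled.

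The series title names mast cell and erythrocyte potential in 1 progenitor, so cells with UMIs of both sets were counted at 1000 UMIs per cell. In the Car1-GFP library, 1.5% of cells had a UMI of the basophil/mast cell set and 71.6% of the erythroid set; 23 cells (0.958%) had both, against 25.8 from the single shares, a ratio of 0.893 (0.566 to 1.34). With so many cells positive for the erythroid set this ratio cannot exceed 1.40, so it says little about whether the sets are independent there. Unthinned, 16.4% had both. In the marrow library 16.1% and 8.62% had each set and 27 cells both against 45.3, a ratio of 0.595 (0.392 to 0.866; 1.71% of cells unthinned). The marrow ratio was 1.12 unthinned and 1.01 with Cpa3 and Ms4a2 alone. Within marrow classes it was 0.912 (0.485 to 1.56) in late erythroid and 1.04 (0.282 to 2.65) in basophil/mast cells. Stem and multipotent progenitors carried both sets in similar shares, 14.6% and 14.2% of 281 cells. There 3 cells had both against 5.84, a ratio of 0.514 (0.106 to 1.5). The ratio was 0.277 in granulocyte-monocyte progenitors and 2.91 in plasmacytoid dendritic cells, each with 1 cell positive for both. The intervals of these class ratios all included 1, so they do not settle whether the sets are independent within a class. The pooled ratio mixes classes that carry 1 set or the other, so it does not show that the sets avoid each other within a class.

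The basophil/mast cell set was present in 1.77% of Car1-GFP erythroid progenitor and 0.451% of late erythroid cells, against 96.6% of the marrow basophil/mast cell class. In marrow neutrophils the share was 16.9%, with the set's Hdc at 119 CPM, and in marrow late erythroid cells 8.64%, with Hdc at 4.89 CPM (median depths 1038.5 and 2569.5). Within the set, Mcpt8 differed most between the libraries (0.514 against 495 CPM), and the tryptase genes Tpsb2 and Tpsab1 had 0 UMIs in both.

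Metabolic genes were left out of the clustering, so their values over classes could be compared with the other cells of the same library. Marrow late erythroid cells had higher carbonic anhydrases (2 of 2 measured, median 5.38), heme synthesis (8 of 9 higher, 1 lower, 3.21) and iron handling (7 of 9, 2.15) and lower glycolysis (2 higher and 8 lower of 15, -1.17; Pkm -3.20 and Hk2 -3.11 lower, Pfkm 3.19 and Hk1 1.85 higher; -2.61 at Leiden resolution 2). Nucleotide and one-carbon synthesis had 9 of 22 higher and 1 lower (0.92, and -0.01 for the late cells with at least 1000 UMIs), and eicosanoid and histamine synthesis was lower (6 of 6, -2.43). The antioxidant (0.88), tricarboxylic acid cycle (0.56), oxidative phosphorylation (0.28), cholesterol synthesis (-0.46) and pentose phosphate (-0.94) medians were within 2-fold.

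In marrow basophil/mast cells, eicosanoid and histamine synthesis was higher (3 of 6, median 1.61; the monoamine transporter Slc18a2 4.56, Hdc 2.79, Alox5 2.60). Hdc and Slc18a2 are also markers of the class, and without them the median was 0.63, within 2-fold. Carbonic anhydrases were lower (2 of 2, -3.72) on 1 Car1 and 2 Car2 UMIs; the other cells here include the late erythroid ones, and neutrophils (12.8 and 16.0 CPM) and monocytes (10.4 and 20.8 CPM) had low values too. Heme synthesis (-0.67), iron handling (-0.68), pentose phosphate (-0.67) and glycolysis (0.16) medians lay within 2-fold. In the Car1-GFP library, late erythroid cells had higher heme synthesis (6 of 9 higher, 1 lower, median 1.36; Alas2 3.04) and lower eicosanoid and histamine synthesis (6 of 7 lower, -1.41) than its other cells, most of which were erythroid progenitors, for which heme synthesis was -1.32. Iron handling (4 of 9 higher, 0.79) and glycolysis (0 higher and 6 lower of 15, -0.77; 0.67 for the progenitors) had medians within 2-fold. Leaving out class markers gave heme synthesis medians of 3.15 (marrow) and 1.36 (Car1-GFP) and iron handling medians of 2.54 and 0.74.

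**Figure D4:**
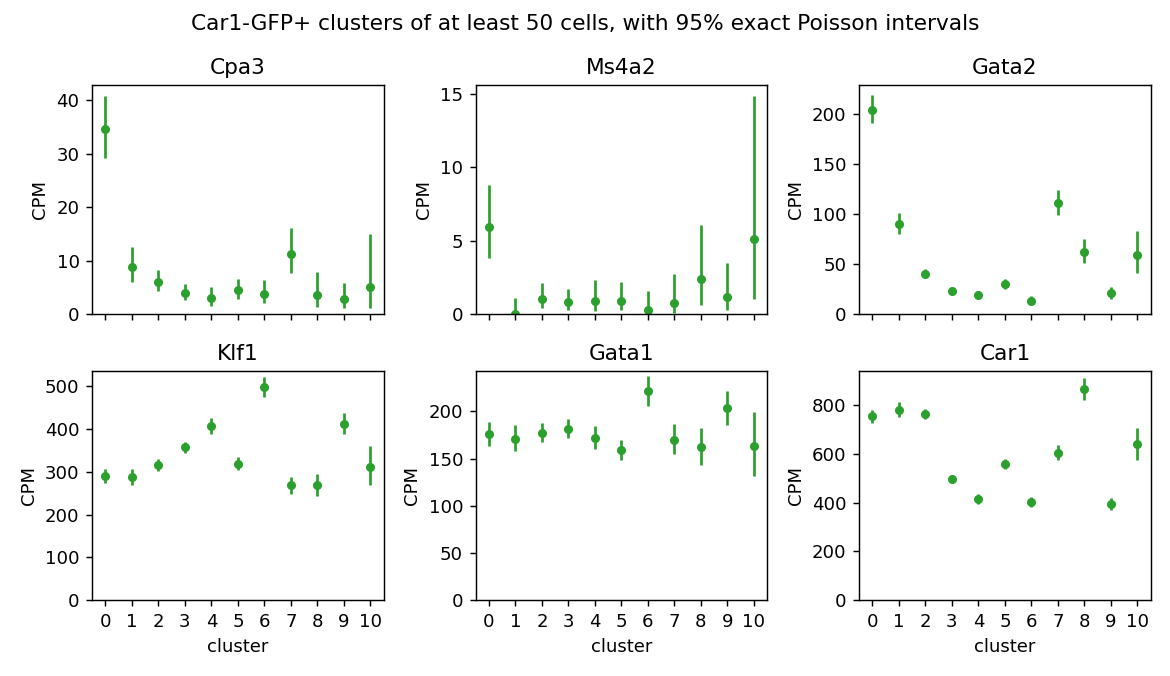
CPM of Cpa3, Ms4a2, Gata2, Klf1, Gata1 and Car1 in Car1-GFP clusters of at least 50 cells, found without the basophil/mast cell and erythroid sets, with 95% Poisson intervals. The mast cell list, which holds Gata2, the basophil list and the metabolic genes were left out of the clustering too. Cpa3 and Ms4a2 stand highest in cluster 0 (568 cells, median 6411 UMIs), where Cpa3 was 34.6 CPM.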

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

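The tests in this part were chosen only after the results were seen. One signal was flagged because it lies in barcodes that the main setting left out, although the alternative with all deposited barcodes used them. The 122 Car1-GFP barcodes left out for 10% or more mitochondrial UMIs had 570 CPM of Car1 (517 to 626), close to the 594 CPM of the kept Car1-GFP cells. The 19 left out of the marrow library had 65.4 CPM (1.66 to 365, 1 UMI).

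Mast cell transcripts appeared in the Car1-GFP library, where no cluster was called basophil/mast cell: 340 Cpa3 UMIs lay in 287 cells. RNA or cells of marrow basophils are argued against by the ratio of Mcpt8 to Cpa3 UMIs, 0.0647 (0.0400 to 0.0996) in the Car1-GFP library and 15 (13.1 to 17.1) in the marrow basophil/mast cell class. A few stray cells or doublets are argued against by the 24 cells with the most Cpa3, which held 19.1% (15.1 to 23.7) of its UMIs. Free RNA spread over all droplets stays open: cluster 0 of 568 cells, found without either gene set and picked as the highest, had 6.71-fold (5.36 to 8.36) the Cpa3 CPM of the other cells, but its cells were shallow (median 6411 UMIs), and per cell the ratio was 2.26 (1.81 to 2.82), whose interval spans the 2-fold set as the limit. No biological explanation was tested, and whether such cells can form mast cells was not measured.

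Immediate early and heat shock genes stood at higher values in the Car1-GFP library (median log2 1.73). The share of erythroid cells in the sort is argued against as the sole cause by the median within late erythroid cells, 2.0 (1.68 to 3.00). With stages split, the median was 3.25 (1.99 to 4.19) between erythroid progenitors and 1.53 (0.33 to 3.39) between late cells. The marrow progenitors had only 6 Jun, 3 Egr1 and 1 Hspa1a UMIs. In the Car1-GFP library Jun was 159 CPM in progenitors and 68.5 CPM in late cells. The classes were not shown to be matched in stage, so a part played by erythroid stage stays open. Handling of the preparation and a property of the cells cannot be told apart with 1 preparation per group.

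Granulocyte transcripts were found in marrow late erythroid cells, and 100% of those 270 cells (98.6 to 100) had an S100a8 UMI. Doublets as the whole cause are argued against by that share. For free RNA the values point in different directions: the mean of 26.5 UMIs per late erythroid cell was 0.895 of the middle one of 3 other classes (29.6), but the medians were 22 and 9 UMIs, 2.44-fold apart. The S100a9 to S100a8 ratio (0.613 in late erythroid cells, 0.654 in neutrophils, 0.554 to 0.742 over classes) did not separate the sources, so free RNA stays open.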

How the results depend on the processing

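Over 22 settings, 184 results gave 1461 alternative values: 1224 stayed within the counting interval, bootstrap interval or limit set for the main value, 236 moved outside it, and 1 of at least 1 in size had the opposite sign. Of 521 log2 values that were at least 1 in size in the main analysis, 520 kept their sign. This tally leaves out some printed values, among them Hbb-bs within late erythroid cells, which turned from 1.46 to -0.54 with at least 1000 UMIs. In it, 27 alternatives to smaller log2 values had the opposite sign, some of them inside the interval, such as the cholesterol synthesis median under TMM (0.26) and DESeq2 (0.25) scaling. No paired analysis was possible because each group has 1 library and no test was made. Depth limits the marrow library: at a median of 1031 UMIs most genes are seen in few cells.

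For the main result of each comparison, the values outside the interval were as follows, and the cause was not tested unless given; the rest of the 236 belong to single genes, classes and lists. With all deposited barcodes, the Car1-GFP erythroid share was 95.1%. With at least 1000 UMIs, the log2 ratio of Car1 was 2.19, the marrow erythroid share 7.36%, and within late erythroid cells Car1 was -0.18 and Kit 0.76, reversed from -3.26; the marrow class then split by stage. TMM factors, which shift all ratios, gave Car1 2.92, heme synthesis 3.48, and within the class 2341 genes higher, 1395 lower and Car1 -0.61; DESeq2 size factors gave 2.92 and 3.48. Equal weight per cell gave 3.64 and 3.32. The Car1-GFP erythroid share and Car1 level were 66.8% and 569 CPM at resolution 0.5 and 89.5% and 605 CPM at resolution 2, where marrow late erythroid glycolysis was -2.61. That share was 85.9% with metabolic genes kept and 90.8% with another seed. In these 4 clusterings the 797, 237, 339 and 220 unnamed cells all scored highest for an erythroid class but failed the naming rule. The score was taken against the marrow library, so it cannot show whether these cells are erythroid or mixed. At the main setting the unnamed cluster 10 also scored highest for an erythroid class. Its top genes within the library nevertheless included the granulocyte genes S100a8 and Elane. Joint clustering gave erythroid shares of 6.94% (marrow) and 99.8% (Car1-GFP) and Car1 at 692 and 608 CPM. Thinning changes both the depth and which marrow cells are deep enough to be used, and the share with a Car1 UMI was 2.14% and 26.7% at 500 UMIs, 14.8% and 67.8% at 2000, and 98.7% of Car1-GFP cells unthinned. Marrow co-detection was 0.871 of chance at 2000 UMIs, 1.12 unthinned and 1.01 with Cpa3 and Ms4a2 alone; requiring 2 UMIs left 0 in the marrow and 0 in the Car1-GFP library. Merging both erythroid classes, chosen after seeing the data, gave Car1 -0.52.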

Other observations

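Cluster 0 of the Car1-GFP library, found without the basophil/mast cell and erythroid sets, could be described by genes that took no part in the clustering. Car1 was 753 against 577 CPM in the other cells and Ms4a2 5.93 against 0.903, the erythroid factors Klf1 290 against 350 and Gata1 176 against 179, and the basophil protease Mcpt8 had 1 UMI (0.247 CPM). Gzmb was 45.2 against 2.04 CPM, Gata2 204 against 39.7, Kit 63.8 against 38.6, Il1rl1 22.5 against 18.9 and Epor 43.0 against 72.6. Of the library's 262 Gzmb UMIs, all lay in 100 cells, with up to 41 in 1 cell. The cells of cluster 0 were 23.7% of the library, shallow (median 6411 UMIs), and held 41.2% of the Cpa3 UMIs with 9.45% of all UMIs. The cluster was picked for the highest Cpa3 CPM, so this share restates the choice. Per cell, its Cpa3 ratio to the other cells was 2.26 (1.81 to 2.82). The clustering was chosen after seeing the data, and these genes outside the naming rule were chosen after their values were seen.

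The megakaryocyte gene Pf4, which encodes platelet factor 4 and was chosen after its values were seen, was at 50.4 CPM in the Car1-GFP library (2155 UMIs in 846 of 2400 cells) and 56.8 CPM in the marrow library (472 UMIs in 84 of 6268 cells), at the unequal depths of these libraries.

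The test in this paragraph was chosen only after the result was seen. Hypothesis: Car1 is lower in late erythroid than in erythroid progenitor cells. The pattern came from the Car1-GFP library (-0.71, -0.77 to -0.66) and was tested in the marrow library with at least 1000 UMIs per cell, 71 late against 181 progenitor cells. There the log2 ratio of Car1 was -1.09 (-1.48 to -0.73), which is consistent with the hypothesis in 1 pool of mice; by cluster of the Car1-GFP library, however, progenitor cluster 7 had 414 CPM of Car1 (394 to 435), overlapping late clusters 5 (392, 375 to 410) and 6 (400, 379 to 422). Alas2 (4.83, 3.07 to 7.23) and Hbb-bs (6.44) marked the later stage. Car2 was higher in the late class of both libraries (0.74, 0.72 to 0.76, and 0.43, 0.24 to 0.62) but not in each cluster. In the Car1-GFP library, late cluster 9 (24 cells) had 1474 CPM (1280 to 1689), overlapping the lowest erythroid progenitor cluster (1573, 1535 to 1612). Progenitor cluster 7 had 4564 CPM, close to late cluster 5 (4530). How GFP protein follows Car1 transcript was not measured.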
